A study of Mus musculus with 9 samples.

How the data were processed

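Expression was measured on 9 Illumina BeadChip arrays, 3 per group, from total RNA labelled with biotin, per the labels. Groups and replicate numbers were taken from the sample titles, which name the stage of each gland. Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. The deposited values used here are intensities on a linear scale that the authors had quantile-normalized across the 9 arrays: sorted columns differed by at most 0.099%, and the lowest value was 42.4, so no background appeared to have been subtracted. The submitters' processing notes name limma, without a version. Scanner software and background correction are not given in the sources used here. A further table of the series held 9 columns of signals and 9 of detection p-values whose names match no sample label, and it was not used here. The design fixed before the data were examined planned background correction and filtering from those columns. The authors' intensities, listed there as an alternative, became the main values instead.

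Of 45281 probes, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 were unnamed here. Entrez identifiers of 34807 named probes matched the RefSeq table of the GRCm38.p6 assembly, and 0 symbols needed an update. Intensities were analysed as log2 values. The background level was set from the mode of all values (66.6) and the spread of values below it, at the 95th percentile of that spread: an intensity of 81.1, or 6.34 on the log2 scale. Probes above it on at least 3 of the 9 arrays were kept, and a gene with several probes was represented by the probe with the highest mean, which left 12716 genes, 5299 of them with more than 1 such probe. Where a group lay below background on every array, the fold is a lower bound, written as at least N-fold, with the background level in place of lower values. Values near the highest log2 intensity on the arrays, 15.63, may understate the level of abundant transcripts.

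Groups were compared in limma 3.58.1 under R 4.3.3, with group means over all 9 arrays, 6 residual degrees of freedom, moderated variances and Benjamini-Hochberg adjustment over the genes tested, at an adjusted p under 0.05. SE is the moderated standard error of the log2 fold change. An exact permutation test of 3 arrays against 3 cannot go below p = 0.1 and was not used. The 34 gene lists were fixed before the data were examined and tested with camera (preset correlation 0.01, adjusted over the lists), with camera at an estimated correlation and with fry, which tests whether the genes of a list move one way and does not compare them with other genes. With an estimated correlation no list passed in any of the 3 comparisons.

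Named genes followed a rule fixed before the data were examined: per comparison the 10 largest changes in each direction among genes past the threshold without overlap between groups, leaving out clone names, up to 4 members of each list past the threshold or else 2 with values only, and a fixed set of tumour suppressor, gland and sex-linked genes. As no gene passed on all 9 arrays, the rule was also applied without normal 3, a choice made after seeing the data. Arrays of a group were compared through 5299 genes measured by more than 1 probe. Log ratios of normal 1 to normal 2 correlated at 0.38 between probes, against 0.74 to 0.81 for the other pairs of arrays within a group. A value above 0 shows a difference beyond probe noise, which separate labellings of 1 RNA would also give, so it does not show that these arrays came from separate glands. They were counted as 2 because the labels name them as separate samples.

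The comparisons were tested on simulated data of 12716 genes, 200 of them changed, for dysplasia against normal. With all 9 arrays 16.4% of log2 changes of 1, 67.2% of changes of 2 and 93.9% of changes of 4 were recovered, with 8 calls among unchanged genes. Without normal 3 these shares were 14.9%, 73.1% and 95.5%. The changed genes were drawn at random with independent noise, so they carried the spread of a typical gene. On the real arrays normal 3 widens the spread of the genes that differ, so the shares for all 9 arrays do not apply to those genes. Alternatives covered log2 of the signal plus 16, no filter, the mean over probes, only the arrays compared, array weights, a replicate block, leaving out each array and, added after seeing the data, normexp, a stricter filter, cyclic loess and centring on tested genes. Figures were drawn with matplotlib 3.10.9.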

Results

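Gene expression was measured in submandibular salivary glands of Smgb-Tag mice, a transgenic line whose transgene expresses the SV40 large T antigen in the gland, a viral oncoprotein that binds the RB and p53 proteins. The series comprised 9 Illumina BeadChip arrays, 3 from glands labelled normal, 3 from glands with dysplasia and 3 from adenocarcinomas, all carrying the transgene. Each array gave intensities for 45281 probes, and 12716 genes with a probe above background on at least 3 arrays were compared on the log2 scale. Every array held the same set of intensities after the authors' normalization (median 80.7, highest 15.63 on the log2 scale), with 22489 probes above background on each. The number of arrays, 3 per group, limits the precision. The brighter probe of the Y-linked gene Eif2s3y gave log2 intensities of 10.15 to 11.17 on the 9 arrays and the other one 6.26 to 6.51, above background on 5 arrays, whereas no Xist probe lay above background on more than 2 arrays.

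The array labelled normal 3 stood apart from the other normal arrays. Normal 1 and normal 2 correlated at r = 0.992 over the tested genes, and 90 genes differed by at least 2-fold between them. Normal 3 correlated with normal 1 and normal 2 at 0.868 and 0.877, but with dysplasia 2 at 0.969 and with adenocarcinoma 2 at 0.972 (genes are not independent replicates, and these values describe pairs of arrays). Normal 1 and 2 in turn correlated with every array except each other at 0.813 to 0.912, so they stood apart as well. A gene that differs only on those 2 arrays is not shown to follow the stage. Cdkn2a, which encodes the cell cycle inhibitor p16 and the p53 activator ARF, had log2 intensities of 6.06 and 6.04 on normal 1 and 2, below the background level of 6.34, and 10.56 on normal 3, against 10.78 to 11.25 in dysplasia and 10.08 to 11.07 in adenocarcinoma. Normal 3 is called by its label throughout, and the comparisons with normal glands are given on all 9 arrays and without it. It was left out after its values were seen, which widens the difference between groups and leaves 2 nearly equal normal arrays, so the p-values and counts without it are too favourable and describe those arrays alone.

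**Figure D1:**
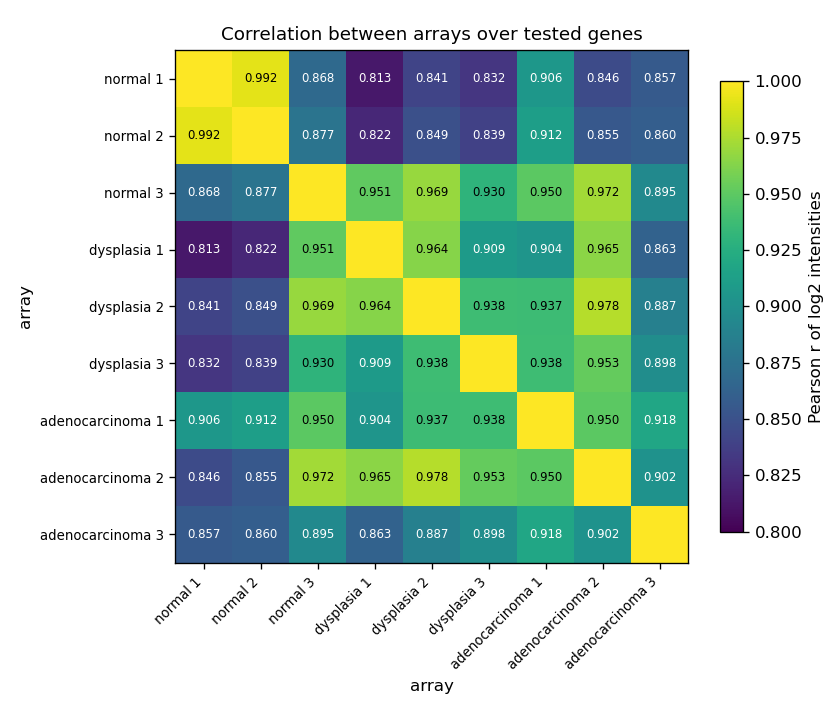
Pearson correlation of log2 intensities over 12716 tested genes for each pair of the 9 arrays, with rows and columns in the order of the groups and the colour scale running from 0.8 to 1. Normal 3 has r = 0.972 with adenocarcinoma 2 and 0.868 with normal 1.

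The comparison of dysplasia with normal glands addressed which genes accompany the change from normal to dysplastic tissue. Genes of DNA replication and cell division were high on all 3 dysplasia arrays and on normal 3, and low on normal 1 and 2. The median log2 intensity of 36 E2F targets, genes of DNA replication and S phase, was 7.92, 8.14 and 11.45 on normal 1, 2 and 3, and 11.60, 11.55 and 10.75 on dysplasia 1, 2 and 3. Of 23 acinar secretory genes, 13 were lower on every dysplasia array than on any normal array, as were 12 of 14 tubule products. Among them amylase (Amy1) was at 15.38, 15.14 and 13.73 on the normal arrays and at 9.06, 7.26 and 6.74 on the dysplasia arrays. No gene passed an adjusted p of 0.05 in limma on all 9 arrays (lowest adjusted p = 0.098), although 2823 genes had an unadjusted p under 0.05, of which 1535 were higher and 1288 lower in dysplasia. Without normal 3, 3017 genes passed, 1584 higher and 1433 lower, and 2090 of them differed by at least 2-fold. Groups did not overlap for 2902 genes on all 9 arrays, or 22.8%, where chance gives 10% on average over splits of the arrays. Genes move together, so a single split can exceed that share by chance. A split that put normal 1 and 2 with dysplasia 3 gave 3259 genes at an unadjusted p under 0.05, more than the real 2823.

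Without normal 3, the largest increases in dysplasia included Dlk1, a membrane protein of the Notch ligand family, with a log2 fold change of 8.37 ± 1.37 (SE, adjusted p = 0.0072), and the LIM domain protein gene Csrp1, 44.2-fold higher at a log2 fold change of 5.47 ± 0.21 (adjusted p = 0.00017). Cdkn2a rose at least 25.1-fold (adjusted p = 0.00077), Otx1, a homeobox transcription factor, at least 25.2-fold (adjusted p = 0.0018), and Il1rn, the interleukin-1 receptor antagonist, at least 36.8-fold (adjusted p = 0.038), all 3 against normal arrays at background. Ret, the receptor for GDNF family ligands, rose by a log2 fold change of 4.89 (adjusted p = 0.0059). Spag5, Pbk, Cdc20 and Kif22, which act in mitosis, rose 31.9-fold, 27.8-fold, 25.5-fold and 25.2-fold. The same comparison on all 9 arrays gave log2 fold changes of 5.54 ± 2.31 for Dlk1 (adjusted p = 0.21), 3.58 ± 1.34 for Csrp1 (adjusted p = 0.19) and 3.44 ± 1.09 for Cdkn2a (adjusted p = 0.17).

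Of 34 gene lists, 4 were called higher and 10 lower in dysplasia by camera on all 9 arrays, and the lists of cell division genes were among the higher ones. Of 36 measured E2F targets, 34 rose without normal 3 and none fell, and 36 rose when adjusted over the list alone. Examples were the chromatin assembly factor Chaf1b (log2 fold change 4.52), thymidine kinase Tk1 (4.32) and the replicative helicase subunit Mcm6 (4.12). Of 30 mitosis genes, 28 rose (30 adjusted over the list alone), among them the kinase Plk1 at 4.58. Of 18 DNA repair genes 12 rose (16 adjusted over the list alone), among them the checkpoint mediator Clspn at 3.33. On all 9 arrays no member of these 3 lists passed, over all genes or adjusted over the list alone, and the median log2 fold changes were 1.82, 2.27 and 1.34. The camera test, with a preset correlation between genes, called each of these lists higher on all 9 arrays (adjusted p = 3.1e-09, 1.2e-08 and 5.5e-05). None of these calls held with an estimated correlation (adjusted p = 0.66 for each). Ribosomal protein genes were also called higher by camera (median log2 fold change 0.24, adjusted p = 0.0073), not with an estimated correlation (adjusted p = 0.66). Rb1 had a log2 fold change of 0.52 ± 0.30 (adjusted p = 0.33) and Cdkn1a, the cell cycle inhibitor p21, one of 0.17 ± 0.78 (adjusted p = 0.92). Trp53, Mki67 and Smgb were not analysed here, as no probe named for them was tested.

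Without normal 3, Amy1 fell 190-fold (log2 fold change -7.57 ± 1.11, adjusted p = 0.005) and Smr3a, a salivary prohormone-like protein, fell 198-fold (-7.63 ± 1.33, adjusted p = 0.0088). The secreted proteins Dnase1, Cst10, Chia1 and Scgb1b27 fell with log2 fold changes of -8.66, -8.00, -6.91 and -7.06. Dnase1 lay above background on 1 of the 3 dysplasia arrays and Scgb1b27 on 2, and such falls to background may be understated. The tubule kallikreins Klk1b1 and Klk1b24 (-7.92 and -7.03) and the major urinary protein genes Mup2 and Mup5 (-6.74 and -6.48) fell as well. Members of these families are near-identical, and their probes may not tell them apart. Of 23 acinar secretory genes 8 fell without normal 3 (12 adjusted over the list alone), and on all 9 arrays none passed (7 lower adjusted over the list alone). The camera test called this list lower on all 9 arrays (median log2 fold change -2.40, adjusted p = 1.2e-06), not with an estimated correlation (adjusted p = 0.32), and the fry test called it as well. The 14 products of the granular convoluted tubule, the androgen-dependent duct segment, had a median of -5.46 (camera adjusted p = 6.3e-07), with 0 members past the threshold over all genes and 12 lower adjusted over the list alone, and an adjusted p = 0.66 with an estimated correlation. Normal 3 had a tubule median of 14.13, next to 15.22 and 15.26 on normal 1 and 2. Epidermal growth factor, Egf, a tubule product, was at 14.82 ± 0.77 (SD, n = 3) in normal glands and 9.65 ± 2.15 (SD, n = 3) in dysplasia, a log2 fold change of -5.17 ± 1.56 (adjusted p = 0.16). The water channel gene Aqp5 had a log2 fold change of -0.17 ± 0.67 (adjusted p = 0.90).

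The duct list was not called on all 9 arrays (median log2 fold change -0.86, camera adjusted p = 0.054, and adjusted p = 0.66 with an estimated correlation), with 8 of 18 members above 0 and 0 past the threshold over all genes or adjusted over the list alone. Of these 18 duct genes 7 fell and 1 rose without normal 3 (the same counts adjusted over the list alone), among them the transcription factor Elf5 (-5.92 ± 0.55, adjusted p = 0.0014) and the sodium channel subunit Scnn1b (-5.57). All 9 adipocyte genes fell without normal 3, with Cidea and Adipoq at -5.79 and -5.76, against 6 lower on all 9 arrays adjusted over the list alone. Of 9 B and plasma cell genes 7 fell without normal 3 (9 adjusted over the list alone), including Fcmr (-4.33) and Mzb1 (-3.92), and of 11 T cell genes 7 fell and 1 rose (9 and 1 adjusted over the list alone), including Cd3d (-2.52). On normal 1, 2 and 3 the medians were 10.28, 9.44 and 7.43 for adipocytes and 8.39, 8.43 and 6.63 for B and plasma cells. For T cells they were 8.17, 8.23 and 6.82. Part of these falls may thus reflect what the samples of normal 1 and 2 held rather than stage, which was not tested. Camera called adipocytes, B and plasma cells and T cells lower on all 9 arrays (adjusted p = 5.3e-05, 0.00012 and 0.00078), in each case with an adjusted p = 0.66 with an estimated correlation. It also called lower the lists of basal and myoepithelial cells, endothelium, skeletal muscle, the secretory pathway and oxidative phosphorylation. Their adjusted p = 0.0092, 0.028, 0.0046, 0.0092 and 0.00041, and with an estimated correlation the lowest adjusted p = 0.66. Of the 14 lists, endothelium was the 1 no longer called without normal 3 (adjusted p = 0.091). Duct genes were then called lower (adjusted p = 0.049), and RB and p53 pathway and interferon response genes higher (adjusted p = 0.017 and 0.03). With an estimated correlation these 3 lists had an adjusted p = 0.58, 0.42 and 0.76. Of 15 antigen presentation genes 4 fell and 2 rose without normal 3 (the same counts adjusted over the list alone), with a median of 0.22 and no call by camera (adjusted p = 0.83). The class II gene H2-Aa of this list fell by 4.87 on the log2 scale without normal 3 (adjusted p = 0.035), and the secretory regulator Creb3l1 fell by 2.46 (adjusted p = 0.0037).

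**Figure D2:**
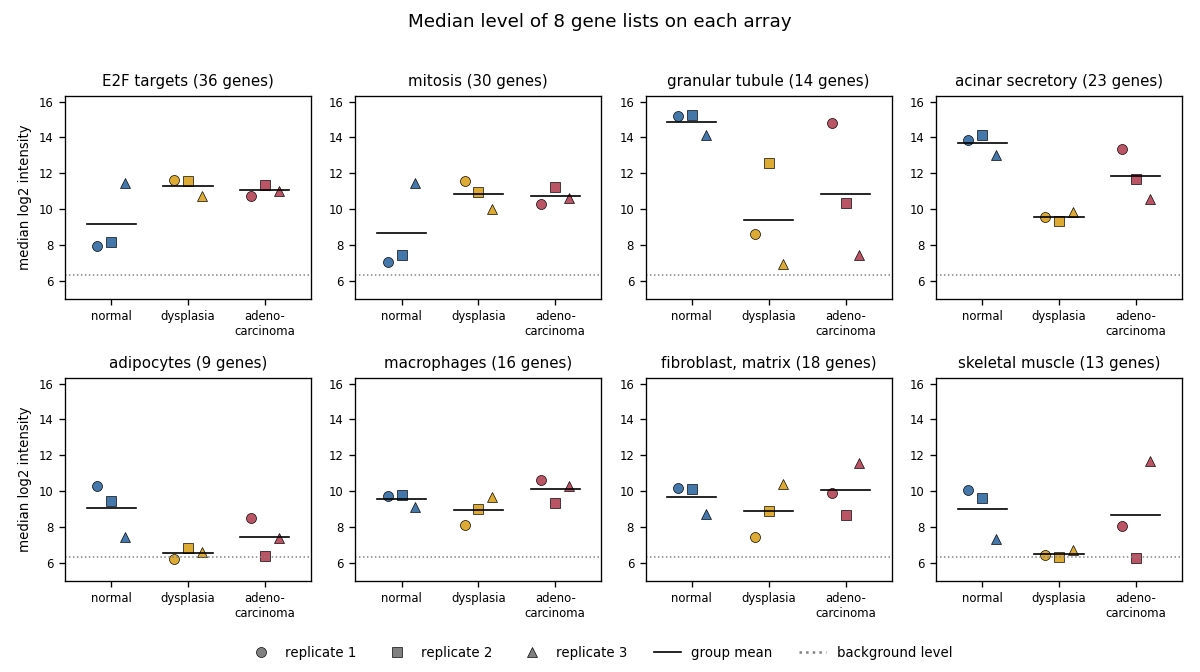
Median log2 intensity of the measured genes of 8 lists (y axis) on each of the 9 arrays, by group (x axis), with a marker per replicate, a line at the group mean and a dotted line at the background level of 6.34. E2F targets lie at 7.92 and 8.14 on normal 1 and 2 and at 11.45 on normal 3, and skeletal muscle genes at 11.68 on adenocarcinoma 3.

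The comparison of adenocarcinoma with normal glands addressed which genes distinguish the tumours from normal tissue. Cell division genes were again high, with E2F target medians of 10.75, 11.36 and 11.02 on the adenocarcinoma arrays. Acinar secretory genes had medians of 13.33, 11.68 and 10.54 there, against 13.87, 14.14 and 13.01 on the normal arrays. No gene passed in limma on all 9 arrays (lowest adjusted p = 0.11), with 2017 genes at an unadjusted p under 0.05, 1023 higher and 994 lower. Without normal 3, 1964 genes passed, 965 higher and 999 lower, 1407 of them by at least 2-fold. Between the groups of 3 arrays, 2563 genes, or 20.2%, did not overlap, where chance gives 10% on average over splits. Splits that put normal 1 and 2 with adenocarcinoma 1 or adenocarcinoma 3 gave 2661 and 2634 genes at an unadjusted p under 0.05. Both counts exceed the real 2017.

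Without normal 3, Csrp1 rose 49-fold in adenocarcinoma (log2 fold change 5.61 ± 0.21, adjusted p = 0.00012), and Mmp12, the macrophage metalloelastase, rose 31.1-fold (4.96 ± 0.59, adjusted p = 0.004). Dlk1 rose by a log2 fold change of 6.08 ± 1.37 (adjusted p = 0.027), with 14.11 and 15.03 on adenocarcinoma 1 and 2 and 9.74 on adenocarcinoma 3. The membrane glycoprotein gene Gpnmb rose 30.4-fold, Otx1 at least 25.8-fold and Cdkn2a at least 20.3-fold. The mitotic genes Spag5, Cdc20, Anln and Kif22 rose with log2 fold changes of 4.92, 4.72, 4.58 and 4.46. Of 36 E2F targets 31 rose (35 adjusted over the list alone), including Chaf1b and Tk1 at 4.18 and 4.09, as did 26 of 30 mitosis genes (27 adjusted over the list alone) and 9 of 18 DNA repair genes (11 adjusted over the list alone). On all 9 arrays these lists had medians of 1.63, 2.18 and 1.01, with 0 members past the threshold either way of adjusting. Camera called them higher (adjusted p = 6.8e-10, 2.1e-09 and 0.0021), not with an estimated correlation (adjusted p = 0.76 for each). Mmp12 had a log2 fold change of 3.96 ± 0.86 on all 9 arrays (adjusted p = 0.22).

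The largest falls without normal 3 were in the secretoglobin gene Scgb1b27 (-6.99), the fatty acid hydroxylase Fa2h (-5.12) and angiotensinogen, Agt (-4.97 ± 0.43, adjusted p = 0.0018). On all 9 arrays their log2 fold changes were -4.69 ± 1.73, -3.70 ± 1.22 and -3.17 ± 1.32 (adjusted p = 0.28, 0.26 and 0.31), with Agt at 6.25 on normal 3 and at 5.93 to 7.44 in adenocarcinoma. The falls without normal 3 also included the osteocalcin genes Bglap and Bglap2 (-4.84 and -4.83), near-identical copies that their probes may not tell apart. Further falls were in the neurotrophin receptor Ngfr (-4.70), the mucin Muc13 (-4.69), the brown fat uncoupling protein Ucp1 (-4.64), the cytochrome P450 gene Cyp2b10 (-4.54) and Bcl2l14 (-4.52). Of 18 duct genes 5 fell and 1 rose without normal 3 (6 and 1 adjusted over the list alone), with Elf5 at -4.09 and the sodium pump regulator Fxyd2 at -4.33. Of 9 adipocyte genes 6 fell (9 adjusted over the list alone), with Cidea at -4.30. The adipocyte median was 7.43 on normal 3, against 8.51, 6.36 and 7.38 on the adenocarcinoma arrays. Of 22 genes of the secretory pathway 9 fell (12 adjusted over the list alone, and 3 on all 9 arrays), with Creb3l1 at -2.87. Camera called duct, adipocyte and secretory pathway genes lower on all 9 arrays (adjusted p = 0.028, 0.0013 and 0.00015), with an adjusted p = 0.76 with an estimated correlation for each. Acinar and tubule products had medians of -1.17 and -3.95 and were called lower too (adjusted p = 0.00064 and 0.00012), again with an adjusted p = 0.76 with an estimated correlation. Without normal 3, 2 of 23 acinar genes fell (0 adjusted over the list alone). Tubule medians spread from 7.42 on adenocarcinoma 3 through 10.34 to 14.82 on adenocarcinoma 1, and no tubule gene passed over all genes or adjusted over the list alone.

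In adenocarcinoma against normal, camera called 7 lists higher and 8 lower on all 9 arrays. Macrophage genes were among the higher lists (median 0.63, adjusted p = 0.0013), with 15 of 16 members above 0 and 0 past the threshold over all genes or adjusted over the list alone. The adjusted p = 0.76 with an estimated correlation. The list median was 10.65, 9.35 and 10.28 on the adenocarcinoma arrays and 9.72, 9.79 and 9.12 on the normal arrays. Adenocarcinoma 2 thus lay below normal 1 and 2. Cd84, a leukocyte surface receptor of this list, rose 3.26-fold without normal 3 (adjusted p = 0.046). T cell genes (median -0.46, adjusted p = 0.019), B and plasma cell genes (-0.98, adjusted p = 0.0086) and oxidative phosphorylation genes (-0.28, adjusted p = 0.0065) were called lower. Ribosomal protein genes (0.29, adjusted p = 0.0062), interferon response genes (0.85, adjusted p = 0.0087) and matrix remodelling genes (0.73, adjusted p = 0.042) were called higher. With an estimated correlation these 6 lists had an adjusted p = 0.81 for the interferon genes and 0.76 for the others. Interferon medians were 8.14, 8.35 and 10.31 on the normal arrays and 10.57, 9.12 and 8.94 on the adenocarcinoma arrays. Matrix remodelling was the 1 list of the 15 no longer called without normal 3 (adjusted p = 0.071). Basal and myoepithelial genes were then called lower and RB and p53 pathway genes higher (adjusted p = 0.038 and 0.0056), with an adjusted p = 0.74 and 0.37 with an estimated correlation. Egf had a log2 fold change of -3.77 ± 1.56 (adjusted p = 0.31), Aqp5 of -1.41 ± 0.67 (adjusted p = 0.34), Cdkn1a of 0.98 ± 0.78 (adjusted p = 0.54) and Rb1 of 0.23 ± 0.30 (adjusted p = 0.73).

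**Figure D3:**
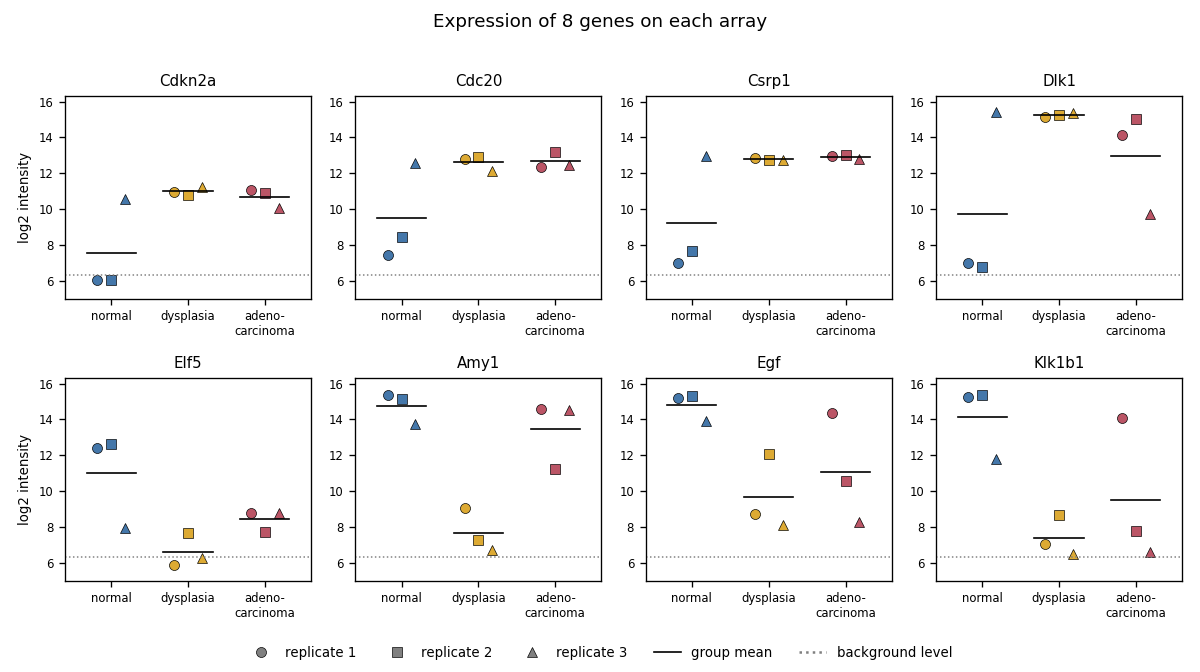
Log2 intensity of 8 genes (y axis) on each of the 9 arrays by group (x axis), with a marker per replicate, a line at the group mean and a dotted line at the background level of 6.34. Cdkn2a lies at 6.06 and 6.04 on normal 1 and 2 and at 10.56 on normal 3, and Amy1 lies at 6.74 to 9.06 in dysplasia and at 11.24 to 14.57 in adenocarcinoma.

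The comparison of adenocarcinoma with dysplasia addressed the change from dysplastic tissue to tumour. Cell division genes were not called as groups, with median log2 differences of -0.22 for E2F targets and -0.15 for mitosis genes (camera adjusted p = 0.49 and 0.59). Camera called macrophage, fibroblast, skeletal muscle and acinar genes higher in adenocarcinoma as groups, none of them with an estimated correlation (adjusted p = 0.73 for each). Not every array followed: the skeletal muscle median was 6.28 on adenocarcinoma 2, below the 6.31 to 6.74 in dysplasia, and 14 of 23 acinar genes were above 0. The macrophage median was 9.35 on adenocarcinoma 2 and 9.70 on dysplasia 3. No single gene passed in limma (lowest adjusted p = 0.89), with 537 genes at an unadjusted p under 0.05, 260 higher and 277 lower, and 1346 genes, or 10.6%, without overlap where chance gives 10%. Without normal 3 the count was again 0 (lowest adjusted p = 0.11), with 871 genes at an unadjusted p under 0.05. Camera then called 15 lists. It added DNA repair genes as lower (median -0.31, adjusted p = 0.019) and adipocyte and growth factor and receptor genes as higher (adjusted p = 0.016 and 0.038). With an estimated correlation each of the added lists had an adjusted p = 0.74.

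Of 34 lists, camera called 11 higher and 1 lower in adenocarcinoma. Macrophage genes had a median log2 difference of 1.10 (adjusted p = 4.7e-10), with 14 of 16 members above 0 and 6 past the threshold adjusted over the list alone, and an adjusted p = 0.73 with an estimated correlation. Ly86 and the lysozyme gene Lyz2, both macrophage genes, had differences of 1.58 ± 0.50 and 1.43 ± 0.77 (adjusted p = 0.89 for each). Fibroblast genes (median 1.09, adjusted p = 1.6e-05), skeletal muscle genes (1.75, adjusted p = 1.4e-05), genes of mesenchymal transition (0.69, adjusted p = 0.0013) and endothelial genes (0.54, adjusted p = 0.0037) were called higher, and epithelial junction genes lower (-0.45, adjusted p = 0.0068). With an estimated correlation each of these 5 lists had an adjusted p = 0.73, and none of their members passed either way of adjusting. Adenocarcinoma 3 held the highest values: Myl1 and Pvalb, genes of fast skeletal muscle, were at 14.20 and 12.33 there, against 10.48 and 8.17 on adenocarcinoma 1 and 6.88 and 6.19 on adenocarcinoma 2. The same array held the lowest Esrp1, an epithelial splicing regulator, at 9.36, against 13.51 to 13.92 on the other adenocarcinoma and dysplasia arrays. The matrix proteoglycan Dcn, the junction protein Ocln and the transcription factors Snai2 and Zeb2 had differences of 2.16, -1.21, 1.19 and 1.15 (adjusted p = 0.89 for each). Without adenocarcinoma 3 none of these 5 lists was called: the medians were 0.28 for skeletal muscle (adjusted p = 0.16), 0.32 for fibroblast (adjusted p = 0.055), 0.38 for mesenchymal transition (adjusted p = 0.055), 0.20 for endothelial (adjusted p = 0.28) and -0.02 for epithelial junction genes (adjusted p = 0.95). Without dysplasia 1, camera called 6 of the 34 lists.

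Acinar secretory genes had a median difference of 0.49 (camera adjusted p = 0.0046), with 6 of 23 members higher adjusted over the list alone, and tubule products one of 1.53 (adjusted p = 0.0086), with 0 members past the threshold. With an estimated correlation the adjusted p = 0.73 for the acinar list and 0.74 for the tubule list. Without adenocarcinoma 3 these medians were 1.29 and 2.76. The tubule median was 14.82, 10.34 and 7.42 on the adenocarcinoma arrays and 8.62, 12.56 and 6.92 on the dysplasia arrays. Without adenocarcinoma 1, camera called 8 of the 34 lists, 6 higher and 2 lower. Smr3a was at 15.63, 11.68 and 15.46 on the adenocarcinoma arrays and at 9.55, 7.28 and 6.53 on the dysplasia arrays, a difference of 6.47 ± 1.12 (adjusted p = 0.89), and Cst10 differed by 6.08 ± 1.39 (adjusted p = 0.89). Basal and myoepithelial, T cell, B and plasma cell and immediate early genes were also called higher (adjusted p = 0.045, 0.045, 0.02 and 0.045), with an adjusted p = 0.73 with an estimated correlation for each. The B and plasma cell median was 7.98, 6.29 and 6.72 on the adenocarcinoma arrays and 6.28, 6.34 and 6.53 on the dysplasia arrays. Without adenocarcinoma 3 the immediate early genes were no longer called (adjusted p = 0.064), whereas interferon response and oxidative phosphorylation genes were called higher and hypoxia and glycolysis genes lower (medians 0.94, 0.14 and -0.41, adjusted p = 3.9e-05, 0.0061 and 0.00025). With an estimated correlation each of these 3 had an adjusted p = 0.74. The interferon median was 10.57 and 9.12 on adenocarcinoma 1 and 2, against 8.60, 9.87 and 8.77 on the dysplasia arrays, so adenocarcinoma 2 lay below dysplasia 2. Cdkn2a differed by -0.31 ± 1.09 (adjusted p = 0.97), Egf by 1.41 ± 1.56, Aqp5 by -1.25 ± 0.67, Cdkn1a by 0.80 ± 0.78 and Rb1 by -0.29 ± 0.30 (adjusted p = 0.89 for these 4).

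Changes in dysplasia and in adenocarcinoma against the same normal arrays were set side by side. Without normal 3, 861 genes were higher and 891 lower in both, and none passed in opposite directions. Independent lists of these sizes would share 120 and 113. In 100 simulations of unchanged groups against the same normal arrays at most 0 calls were shared, which sets no level for lists of this size, as 0 genes were called in simulated data without changes for dysplasia against normal. On all 9 arrays no gene passed in both. The log2 fold changes of the 2 comparisons correlated at 0.79 over genes on all 9 arrays, where unchanged groups gave 0.50, with a covariance of 0.43 against 0.09 in the simulations. Without normal 3 the correlation was 0.90 against 0.60 and the covariance 0.94 against 0.10. The normal arrays were not divided between the 2 comparisons, so part of the overlap may come from the shared normal arrays.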

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

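Normexp, the stricter filter, cyclic loess and centring were chosen after seeing the data, and the planned detection p filters, correction from detection p-values, median scaling (which moves nothing on quantile-normalized values) and BeadChip block (no slide given) were not run. For genes in dysplasia, in adenocarcinoma and in both against normal, the count of 0 became 1, 6 and 1 without a filter, and 7787, 4490 and 3919 with array weights, which gave normal 3 a weight of 0.17. Array weights called 4 genes and 19 lists between adenocarcinoma and dysplasia, and cyclic loess 1 gene between adenocarcinoma and normal. Leaving out 1 array gave 0 to 3017 genes for dysplasia, 0 to 1964 for adenocarcinoma, 0 to 1752 for both and 0 to 1 between adenocarcinoma and dysplasia. The maxima for dysplasia, for adenocarcinoma and for both came without normal 3. Counts at an unadjusted p under 0.05 moved as well when 1 array was left out. They ran from 1179 to 4794 for dysplasia, 863 to 3984 for adenocarcinoma and 291 to 1119 between adenocarcinoma and dysplasia. Without dysplasia 1, 2 genes passed for dysplasia and 1 between adenocarcinoma and dysplasia, and without adenocarcinoma 2, 5 for dysplasia and 1 in each other comparison. Lists called fell from 14, 15 and 12 to 0, 0 and 0 with an estimated correlation and to 1, 0 and 0 with fry. Without normal 3, fry called 12, 10 and 0 lists and camera with an estimated correlation again 0. The stricter filter left 9 lists for dysplasia, and leaving out 1 array gave 6 to 16 lists between adenocarcinoma and dysplasia, lowest without dysplasia 1. With a replicate block 0 genes passed in each comparison and in both, and 15, 16 and 11 lists were called. Of 9 pairs of arrays with equal replicate numbers, 2 had deviations from the group means correlated over 0.1 (highest 0.24). Adenocarcinoma 2 and normal 3, with unequal numbers, reached 0.51. Normal 1 and 2 deviate alike from a mean shifted by normal 3, so this check cannot exclude pairing by number. Leaving out 1 array gave -0.34 to 0.04 for Aqp5 in dysplasia, positive without normal 3. Cdkn1a in dysplasia turned to -0.26 with array weights and -0.083 by probe ILMN_2846776, and leaving out 1 array gave -0.86 (without dysplasia 3) to 0.71, with -0.15 without normal 2. Between adenocarcinoma and dysplasia, Cdkn2a turned to 0.069 with array weights and 0.001 by ILMN_1221177, and leaving out 1 array gave -0.24 (without adenocarcinoma 1) to 2.79 for Egf. Rb1 in adenocarcinoma against normal turned to -0.22 by ILMN_2679619. Apart from those settings whose construction shows it, the cause was not tested. Of 1404 values of named genes under alternatives, 9 changed sign. Many of these genes were named for large differences on these same arrays, so the low number of sign changes says little. A further 126 values passed an adjusted p of 0.05 in limma where the main fit did not, 61 of them without normal 3. Fold changes near background may be understated, as the lowest value of 42.4 gives no sign that background was subtracted. The sources used here do not state it.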

Other observations

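The tests of normal 3 and of the gland products were chosen only after those results were seen, and the splits of the arrays before. The predictions for adenocarcinoma 3 were written before their tests were run. They name 1 array, so they cannot count as fixed before the array levels were seen. Several lists varied between arrays of 1 group. The median of 18 interferon response genes was 10.31 on normal 3, 9.87 on dysplasia 2 and 10.57 on adenocarcinoma 1, and 8.14 to 9.12 on the other 6 arrays. Genes of matrix remodelling reached a median of 11.64 on dysplasia 3, where Il1rn was also at 14.41, against 7.88 and 8.40 on dysplasia 1 and 2. Hypoxia and glycolysis genes had a median of 12.40 on adenocarcinoma 3 and 9.50 to 10.99 on the other 8 arrays.

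The array labelled normal 3 carried the cell division programme of the dysplasia and adenocarcinoma arrays. A swap with one of those arrays needs a partner with normal levels, but the lowest of them lay 2.81 above the mean of normal 1 and 2 in the median log2 level of 66 E2F and mitosis genes, which argues against it. A mixture of normal and dysplastic tissue stays open: 980 genes lower in dysplasia put the dysplasia-like share of normal 3 at 0.94 to 0.96 and the tubule products at no more than 0.70 (95% bootstrap interval over genes 0.44 to 0.84), but the tubule products lie so near the top of the intensity range that their share may be too low. A gland with disease that was labelled normal cannot be told apart either. The tubule median of 14.13 lies above the range of the dysplasia arrays, 6.92 to 12.56, where a gland with dysplasia was expected to lie. It lies inside the range of the adenocarcinoma arrays, 7.42 to 14.82, which is too wide to decide. A candidate biological explanation, a transgenic gland that divides before its histology changes, was not tested, as no group of the design separates it. That normal 1 and 2 are instead the odd arrays, for a reason other than stage, was not tested either.

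Medians of parotid and submandibular products lay within 1 of each other (log2) on 7 of 9 arrays and parted on adenocarcinoma 3 and dysplasia 2. In adenocarcinoma 3, 7 products abundant in the parotid gland lay 0.65 below normal 1 and 2 at the median (log2) and 14 submandibular products 7.61 below. The difference was 6.96 (95% bootstrap interval over genes 4.27 to 7.93). That interval treats related genes as independent and holds no spread between arrays. As measured on this 1 array, a single share of remaining gland does not account for both. In adenocarcinoma 1 the difference was -0.04 (-1.80 to 0.67), and a single share may. Medians of both sets were 15.14 to 15.32 on normal 1 and 2, near the highest value of 15.63, so each fall may be understated. Dysplasia 2 had the opposite order, with medians of 7.26 for parotid and 12.73 for submandibular products. Parotid tissue in the dissected pieces would make the parotid products rise and fall together. The lowest rank correlation between any pair of them over the arrays was 0.03, so that pair did not. Parotid tissue stays open as a possible source, because this test rests on the lowest pair. A change within the gland would also move these products. Some of these products are also made by the normal submandibular gland or were on the acinar list, and the 2 lists were written after acinar values were seen.

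Skeletal muscle and stromal genes in the comparison of adenocarcinoma with dysplasia may come largely from adenocarcinoma 3. Without it the higher of the skeletal muscle and fibroblast list medians was 0.32, under the limit of 0.5 set before the test was run. That array had the highest adenocarcinoma medians of both lists, 11.68 and 11.55, so leaving it out lowers the difference by construction. Adenocarcinoma 3 was not the only array with muscle genes, as their median was 8.03 on adenocarcinoma 1 against 6.31 to 6.74 in dysplasia. The normal arrays had medians of 10.06, 9.59 and 7.31, so muscle genes were not particular to the tumours. Macrophage genes kept a median difference of 1.01 without adenocarcinoma 3 (camera adjusted p = 6.5e-09), which argues against adenocarcinoma 3 as their only source. The call was lost with an estimated correlation (adjusted p = 0.74). More macrophages in the tumours stays open as a biological explanation, without a test in this series. Adenocarcinoma 2 had a macrophage median of 9.35, below the 9.72 and 9.79 of normal 1 and 2.

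Splits of the 6 arrays of a comparison into other groups of 3 number 10 with the real one, too few for a share under 0.05. Where the real split calls 0 genes, all 10 splits give at least as many by construction, so the counts of genes past the threshold test nothing. At an unadjusted p under 0.05, another split exceeded the real one in each comparison. The counts were 3259 against 2823 for dysplasia against normal and 2661 against 2017 for adenocarcinoma against normal. For adenocarcinoma against dysplasia they were 2008 against 537. For dysplasia against normal the real split gave 0 genes and 14 lists, 5 splits counting the real one gave at least as many lists, and the highest others were 1 gene and 20 lists. For adenocarcinoma against normal it gave 0 genes and 15 lists, 4 splits counting the real one gave at least as many lists, and the highest others were 172 genes and 15 lists. Those 172 genes came from a split that put normal 1 and 2 with adenocarcinoma 3, which points to a structure of the arrays other than their labels. For adenocarcinoma against dysplasia it gave 0 genes and 12 lists, 7 splits counting the real one gave at least as many lists, and the highest others were 2 genes and 19 lists.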
